A study of Mus musculus with 6 samples.

How the data were processed

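Total RNA was taken from the spleens of 3 Was knockout and 3 wild-type male mice aged 10 weeks, and libraries were made with an mRNA library kit, per the labels' protocols. Each library is 1 animal. The submitters' processing notes name FastQC 0.11.5, STAR 2.5.3a, StringTie 1.3.1c, DESeq and the genome build GRCm38, without saying what each was used for. The counting step, the annotation, the filters and the strand setting are not given in the sources used here.

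The authors deposited 1 table of 26452 genes with a log2 value for each of the 6 libraries, the mean log2 value of each group, and their own comparison of the groups as a log2 fold change, a p-value and an FDR. Each deposited log2 value is the log2 of a read count divided by a size factor of the library, plus 1. That was read from the values: 2 to the power of the value, less 1, was a whole multiple of 1 step per library for 100% of values within a tolerance of 0.001. The steps give back the authors' size factors and whole reads, which total 34567573 for KO451, 33352673 for KO452, 35001679 for KO457, 32235723 for WT453, 38402758 for WT454 and 30661759 for WT455. The size factors were equal to median ratios recomputed from these reads, apart from rounding. The authors' deposited log2 fold change is the difference of the group means of the log2 values. How the deposited p-value and FDR were computed is not stated beyond the name DESeq in the submitters' processing notes. Column names of the knockout libraries end in a suffix that those of the wild-type libraries lack, and what it marks is not stated. If it marks separate processing of the groups, that cannot be separated from genotype.

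Because the deposited values are log2 values of normalized counts, limma 3.58.1 in R 4.3.3 was used, as fixed for normalized values before the data were examined. The test was limma with an intensity trend on log2(normalized count + 1), which is the deposited value, with a 2-group model and no covariate. A gene was tested if its mean normalized count over the 6 libraries was at least 1, which kept 22071 genes and left out 4381. Adjustment was by Benjamini-Hochberg, with a threshold of 0.05. Fold changes on the log2(value + 1) scale understate the change of genes with few reads. The groups share no animal numbers, so no pairing was used. The p-values measure the spread between these animals, and the labels state no batch.

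Gene lists were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation and with fry, all from limma. The 38 lists, 688 genes in all, covered spleen cell types, red cell and iron biology, immunoglobulins, cell cycle, interferon and stress genes, actin regulators, neighbours of Was and neighbouring tissues, and were fixed before the data were examined. A list needed at least 3 measured members. Shares of reads and list means were compared with two-sided exact permutation tests, for which 3 against 3 cannot give a p below 0.1.

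Genes were named by a rule fixed before the data were examined. It takes Was, the 10 largest increases and decreases among genes past the threshold with at least 1 CPM in the higher group and no overlap between the groups, and the 4 smallest p in each direction. It adds up to 4 members of each list past the threshold, and up to 2 with the highest mean in a list with none. It leaves out immunoglobulin and T cell receptor segments, predicted genes, pseudogenes and features with no symbol. After the main test had called 2 genes, the same rule was applied to the FDR of the authors' deposited table, and that table is named wherever its calls are used. Outside the rule, Gm20716, Gm4631, Adnp, Fos, Hba-a1, Ighm, Rag2, Igll1, Vpreb1, Dntt, Mki67, Top2a and the regulators of red cell precursors were named after their values were seen. Some genes that the rule names are not reported here.

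Positions, gene types, overlaps between genes, transcript GC content and transcript length came from the GENCODE annotation of GRCm38, in which 26404 of the 26452 gene identifiers were found. The test was tried on simulated data with the real genes, means and library sizes, in which 200 genes, and a list of 30 more, were changed by known amounts and libraries varied independently. Limma called 4.48% of genes changed 2-fold, 67.2% of genes changed 4-fold and 90.9% of genes changed 16-fold, with 0 calls among the 21841 unchanged genes. Each simulated gene took the median spread of genes at its level, so genes of like level did not differ in spread. The simulation held no library that deviates as a whole, as WT453 does in the real data. The shares called therefore need not hold for the real data.

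Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.01, no filter, a filter at a mean of 1 CPM, quantile normalization, removal of immunoglobulin and haemoglobin genes, each library left out in turn, the other list tests and a threshold of 0.01. Added after seeing the data were limma voom on the recovered reads, library quality weights, robust moderation, scaling by library totals, by upper quartile and by recomputed median ratios, filters at mean normalized counts of 10 and 100, a test against a log2 fold change of 0.5, and WT453 left out together with the filter at 1 CPM. Tests planned for deposited counts were not run, since the deposited values are log2 values, although the recovered reads would have allowed them. Figures were drawn with matplotlib 3.10.9.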

Results

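RNA of the spleen was sequenced from 10-week-old male mice of 2 groups, 3 mice with a targeted Was gene (Was -/-, 129S6/SvEvTac-Wastm1Sbs/J) and 3 wild-type 129S6/SvEvTac mice. Was encodes the Wiskott-Aldrich syndrome protein, an activator of Arp2/3-driven actin assembly that is made in blood cells, and its loss in people causes Wiskott-Aldrich syndrome. The design asks how the spleen transcriptome of knockout mice differs from that of wild-type mice. The knockout libraries are named KO451, KO452 and KO457 and the wild-type libraries WT453, WT454 and WT455, as in the labels. Reads assigned to genes ranged from 30661759 in WT455 to 38402758 in WT454, so that 3 reads, the limit that a count of 0 allows, correspond to between 0.0781 and 0.0978 ppm of the reads assigned to genes (CPM). Such floors cover counting error only.

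Was transcripts were lower in all 3 knockout spleens than in all 3 wild-type spleens, at about 1/12.6 of the wild-type level, but were not absent. The authors' log2 normalized count of Was was 8.78 ± 0.18 (SD, n = 3) in knockout and 12.44 ± 0.37 (SD, n = 3) in wild-type libraries. Mean abundance was 12.4 CPM in knockout and 177 CPM in wild-type libraries. The log2 fold change was -3.66 with a standard error of 0.25 (limma, Benjamini-Hochberg adjusted p = 0.0117). An exact two-sided permutation test of the 3 against 3 values gave p = 0.1, the smallest this design allows. Was (ENSMUSG00000031165) is a protein-coding gene on the minus strand of chromosome X at 8081453 to 8090498 in GRCm38, and a short nuclear RNA gene lies within it on the other strand. The labels do not state which part of the gene the allele alters or which exons the counts cover. Each library carries the Was level its label calls for. The limma call was lost when any of the libraries KO451, KO452, KO457, WT454 or WT455 was left out, with adjusted p between 0.245 and 0.341 and log2 fold changes between -3.76 and -3.53.

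**Figure D1:**
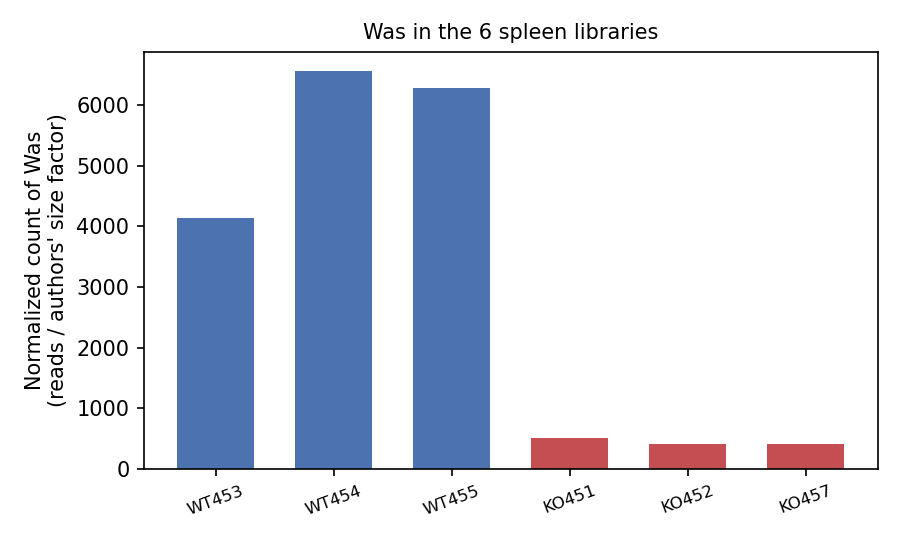
Normalized count of Was (reads divided by the authors' size factor, linear axis from 0) in each of the 3 wild-type (blue) and 3 WAS knockout (red) spleen libraries, 1 bar per library. Every knockout bar lies below every wild-type bar and none is at 0.

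Apart from Was, 1 gene passed the test over all genes. Gm20716 fell to 0 reads in all 3 knockout libraries, against 65.8 ± 58.2 CPM (SD, n = 3) in wild-type libraries, at least 731-fold lower when set against the floor of 3 reads per library, or at least 359-fold without WT453. Its adjusted p was 0.0117 (limma). It was past the threshold in 15 of 23 alternative settings, across which the adjusted p reached 0.381. The call was lost in every voom setting. Gm20716 is a predicted gene outside the rule for named genes and was named after its values were seen. Its model (chromosome 2, 168180986 to 168230364, minus strand) ends at the same base as that of Adnp and also spans Dpm1. Reads of these genes can thus be split between models, and its value is uncertain. In WT453, Adnp had a normalized count of 2.06 and Gm20716 one of 4409, whereas in WT454 Adnp had 3916 and Gm20716 1161. The 2 genes summed to between 3438 and 5077 normalized counts in 5 libraries and to 651 in KO457.

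Of 22071 genes tested, 2 were called, 0 higher and 2 lower in knockout spleens, and both differed at least 2-fold. At an unadjusted limma p under 0.05 there were 2420 genes, 1214 higher and 1206 lower, where 1104 would be due to chance. The mixed split of KO451, KO457 and WT453 against the other libraries gave 3077, so this excess does not set the genotypes apart. The groups did not overlap in 19.5% of genes, where 10% is the chance share for 3 against 3. The next gene, Gm4631, with 0 reads in every knockout library and 2.01 CPM in wild-type libraries, had an adjusted p of 0.0526 (limma). Other limma settings called between 0 and 16 genes. The authors' deposited table lists 948 genes with an FDR under 0.05, 567 higher and 381 lower in knockout spleens, and 741 of them with at least a 2-fold change, 481 higher and 260 lower. Of the 948, 928 had an unadjusted limma p under 0.05 and 2 passed limma's adjusted threshold.

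Because limma called so few genes, the fixed naming rule was also applied to the FDR column of the authors' deposited table, a choice made after the calls were seen. The genes below carry limma's own log2 fold changes and standard errors, and none passed limma's adjusted threshold in the main test except Was. Among the 10 with the largest increases by that rule were 3 genes of the apolipoprotein L cluster on chromosome 15. Apol11b had a log2 fold change of 3.86 ± 0.73 (SE) and a mean of 122 CPM in knockout libraries against 9.96 in wild-type libraries, with a log2 fold change of 4.54 without WT455. Apol11a had one of 3.97 ± 1.12 (2.82 without WT454, 4.70 without KO452 and 4.75 without WT455). Apol10a had 0 reads in all wild-type libraries and 0.420 to 3.96 CPM in knockout libraries, at least 20.5-fold higher against the floor, or 10.5-fold without KO451. Schip1 (5.14 ± 0.93), Pet117 (4.79 ± 0.94), Avpr2, a vasopressin receptor (4.06 ± 0.63), Rnf212 (2.58 CPM in knockout and 0.185 CPM in wild type), Gnai1, a G protein subunit (3.98 ± 0.79), and Slc9b2, a sodium/hydrogen exchanger (3.73 ± 0.53), were under a mean of 4 CPM in both groups, and of these all but Slc9b2 overlap another gene model, so that their reads are uncertain without a stated strand setting. The log2 fold changes without KO451 were 4.31 for Schip1 and 3.30 for Rnf212, without WT453 2.91 for Rnf212 and 5.86 for Pet117, and without WT455 4.59 for Rnf212 and 3.25 for Gnai1. Gnai1 was 4.62 without WT454 and Schip1 6.03 without KO452. Ighe, the constant region of IgE, had a log2 fold change of 4.02 ± 1.14, with 100 CPM in knockout and 4.25 CPM in wild-type libraries. KO457 carries that mean, at 259 CPM against 25.7 in KO451 and 16.6 in KO452, and the log2 fold change was 2.79 without KO457, 3.24 without WT454, 4.84 without KO452 and 4.66 without WT453. The smallest p in the authors' deposited table among increases belonged to Slc9b2, to the ribosomal RNAs of the mitochondrion, mt-Rnr1 (1.67 ± 0.23) and mt-Rnr2 (1.90 ± 0.26), and to the matrix metalloproteinase Mmp27 (2.57 ± 0.40).

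Among decreases by the same rule, Rac1, a small GTPase that controls actin assembly, had a log2 fold change of -1.45 ± 0.19 (SE), from 327 CPM in wild-type to 108 CPM in knockout libraries, with an unadjusted limma p of 8.86e-05 and an adjusted p of 0.344. Ahdc1, a DNA-binding protein gene, had one of -2.65 ± 0.37, from 17.4 to 2.61 CPM. Rgs11, a regulator of G protein signalling (-3.54 ± 0.56), Doc2g (-3.38 ± 0.97), Gpc2 (-3.80 ± 1.15), Sycp2, a protein of meiotic chromosomes (-3.06 ± 0.56), Erp27 (-2.62 ± 0.91) and Mir5107 (-2.52 ± 0.67) were below a mean of 6 CPM in both groups. WT453 had the highest value of the 6 libraries in Doc2g, Gpc2, Erp27 and Mir5107, which without it were -2.35, -2.86, -1.75 and -1.82, and Gpc2 was -2.77 without KO451, -4.46 without KO457 and -4.42 without WT454, and Erp27 -3.20 without KO457 and -3.28 without WT455. The models of Rac1, Rgs11, Doc2g, Gpc2, Mir5107 and Tsga13 overlap another gene. Tsga13 had 0 reads in all knockout libraries and 2.49 ± 3.38 CPM (SD, n = 3) in wild-type libraries, of which WT453 had 6.36. The heat shock gene Hspa1b (-3.33 ± 1.40), which has a near-identical copy in Hspa1a, was high in WT453, at 143 CPM, and the log2 fold change was -1.54 without it and -4.53 without WT455. Left out by the rule among the authors' 948 genes were 129 predicted genes, 12 pseudogenes, 15 features with no symbol and 6 immunoglobulin or T cell receptor segments.

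Red cell genes were the group with the largest difference. Of 30 measured members of the erythroid list, 29 were higher in knockout spleens, with a median log2 fold change of 2.58, and the list rose by camera with a preset correlation (adjusted p = 2.79e-27) but not with an estimated correlation (adjusted p = 0.747). Adjusted over the list alone, 29 members passed, over all genes 0 passed, and the authors' deposited table lists 26 at an FDR under 0.05. The members varied together (estimated correlation 0.76), so the 29 are not independent results. For the library means of the list, an exact permutation test gave p = 0.1, and 0.633 after adjustment over the lists. Examples are Epb42, a red cell membrane protein (2.94 ± 0.58 SE, 2.26 without KO451), Klf1, a transcription factor of the red cell lineage (2.78 ± 0.52), and Car2, carbonic anhydrase (2.73 ± 0.50). Haemoglobin transcripts took 4.31% ± 2.65 (SD, n = 3) of reads in knockout and 0.691% ± 0.473 (SD, n = 3) in wild-type libraries. An exact two-sided permutation test gave p = 0.1 for that share, and 0.3 after adjustment over 6 shares. Hba-a1, an alpha globin with a near-identical copy, had a log2 fold change of 2.75 ± 0.61. Haemoglobin was highest in KO451, at 7.36%, and lowest in WT453, at 0.204%. Without KO451 the median of the list was 1.96. Without WT453 it was 2.29 and 20 members passed adjusted over the list alone.

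**Figure D2:**
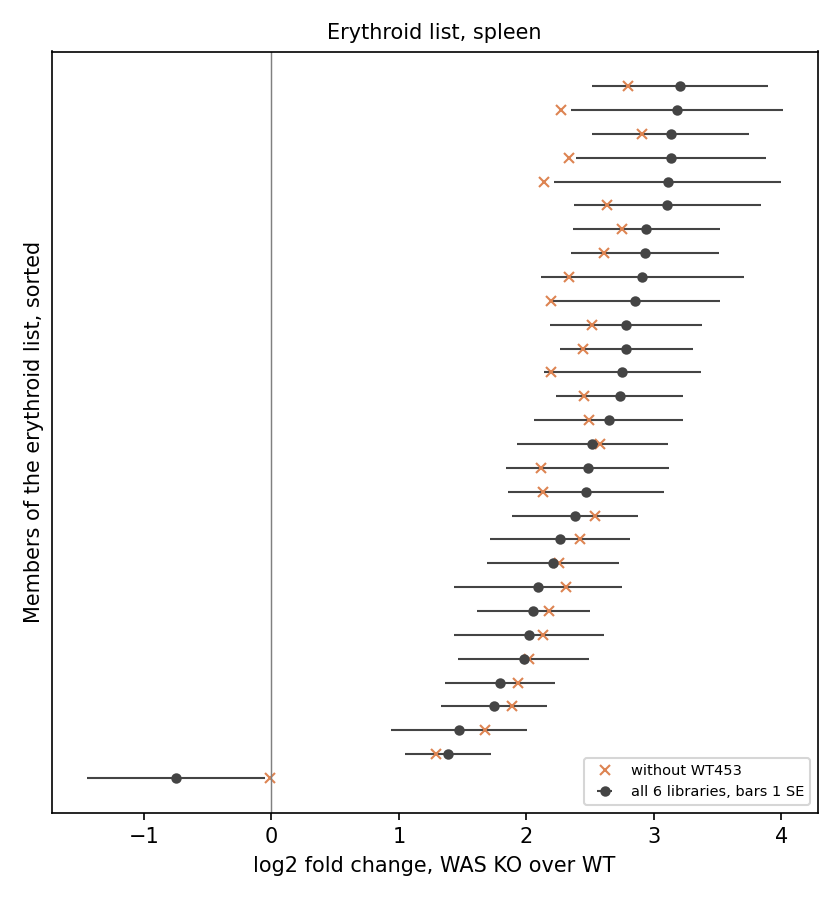
Log2 fold change (WAS knockout over wild type, x axis) of the 30 measured members of the erythroid list (y axis, 1 line per member, sorted by fold change, not labelled). Circles with bars give the limma estimate and 1 SE over all 6 libraries, crosses the estimate without WT453. All members but 1 lie above 0, and the median is 2.58.

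Enzymes of heme synthesis and genes of iron handling moved in the same direction. Of 9 heme synthesis enzymes 8 were higher, with a median of 1.71, and the list rose by camera (adjusted p = 4.59e-07, adjusted p = 0.747 with an estimated correlation). Adjusted over the list alone 7 passed, over all genes 0. Fech, which inserts iron into protoporphyrin to form heme (2.32 ± 0.57 SE), Cpox (2.05 ± 0.47) and Alad (1.71 ± 0.44) are examples. Without WT453, none of the 9 passed adjusted over the list alone, although the median stayed at 1.76. All 16 iron handling genes were higher, with a median of 1.10 (camera adjusted p = 7.85e-09, adjusted p = 0.747 with an estimated correlation). Adjusted over the list alone 5 passed, over all genes 0. The biliverdin reductases Blvrb (1.87 ± 0.35) and Blvra (1.49 ± 0.35), ferritin heavy chain Fth1 (1.02 ± 0.31) and Tfr2, a transferrin receptor (1.43 ± 0.41), were among them. Genes of red pulp macrophages, the spleen cells that take up old red cells, were higher in 21 of 21 members with a median of 1.16, and the list rose by camera (adjusted p = 4.51e-09, adjusted p = 0.858 with an estimated correlation). Cd5l, a protein secreted by macrophages, had a log2 fold change of 1.97 ± 0.39 and was the 1 member that passed adjusted over the list alone. Over all genes 0 members passed. WT453 was the lowest library in that list, 1.63 below the mean of the 6 on the log2 scale, and without it the median was 0.48 for red pulp macrophages and 0.68 for iron handling, and 0 members of either list, Cd5l included, passed adjusted over the list alone.

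Cell cycle genes were higher in 35 of 35 members, with a median log2 fold change of 1.10, and the list rose by camera (adjusted p = 9.53e-13, adjusted p = 0.858 with an estimated correlation). Over all genes 0 members passed and adjusted over the list alone 0. The library means of this list overlapped between the groups (exact permutation p = 0.3). Against the mean of the 6 libraries on the log2 scale, KO451 was at 1.39, WT453 at 0.48, KO457 at 0.46 and KO452 at -0.15. Without WT453, which was above the mean of the 6 libraries in this list, the median was 1.62 and 28 members passed adjusted over the list alone. The median was 0.70 without KO451 and 0.73 without WT454. Cdc6 (1.88 ± 0.48 SE) and Mcm2 (1.10 ± 0.36), which license DNA replication, the cyclin Ccnb1 (1.66 ± 0.43) and E2f2 (1.24 ± 0.45) are listed at an FDR under 0.05 in the authors' deposited table. The 13 messenger RNAs of the mitochondrial genome were all higher (median 0.98, camera adjusted p = 1.88e-04, adjusted p = 0.858 with an estimated correlation), and 0 passed adjusted over the list alone or over all genes. In WT453 they lay 2.08 below the mean of the 6 libraries on the log2 scale. Without that library the median was 0.18 and the call was lost (adjusted p = 0.111), as it was in voom with quality weights (0.0642). Megakaryocyte and platelet genes were higher in 17 of 25 members (median 0.37, camera adjusted p = 0.0262, adjusted p = 0.858 with an estimated correlation), with 0 members passing either adjustment. That call was also lost without WT453 (median 0.30, adjusted p = 0.243), without KO452 (0.28, adjusted p = 0.219) and without KO457 (0.42, adjusted p = 0.129). It was lost as well with filters at 1 CPM (adjusted p = 0.0885) and at mean normalized counts of 10 (0.0573) and 100 (0.182), and in voom with a filter at 1 CPM, robust (0.0849) or with quality weights (0.155). Its member Gp9, a platelet surface protein, had a log2 fold change of 1.66 ± 0.47.

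T cell genes were lower in 24 of 25 members with a median of -0.58, and the list fell by camera (adjusted p = 4.18e-05, adjusted p = 0.858 with an estimated correlation). Lat, an adaptor of T cell receptor signalling (-1.19 ± 0.32 SE), and Satb1 (-1.03 ± 0.23) are listed at an FDR under 0.05 in the authors' deposited table. B cell genes were lower in 16 of 18 members (median -0.64, camera adjusted p = 0.00312, adjusted p = 0.858 with an estimated correlation), among them Cd37 (-1.09 ± 0.30). Genes of NK and cytotoxic cells were lower in 15 of 17 members (median -0.45, camera adjusted p = 0.0273, adjusted p = 0.858 with an estimated correlation), among them Nkg7, a granule protein (-0.82 ± 0.26). In these 3 lists 0 members passed over all genes and 0 adjusted over the list alone. The library means of each list overlapped between the groups (exact permutation p = 0.4 for each list), with KO452 between 0.19 and 0.27 above the mean of the 6 libraries on the log2 scale. WT453 had the lowest mean of the 6 libraries in each of these lists. Without it the medians were -1.10 for T cells, -1.09 for B cells and -0.92 for NK and cytotoxic cells, and 15 T cell, 0 B cell and 9 NK cell members passed adjusted over the list alone. The T cell call was lost without WT454 (adjusted p = 0.0506, median -0.37), and without WT455 the median was -0.32. The B cell call was lost without KO451 (adjusted p = 0.0633, median -0.47), without WT454 (0.267, median -0.24) and without WT455 (0.0997, median -0.39). The NK cell call was lost without KO451 (0.167, median -0.28), KO457 (0.124, median -0.38), WT454 (0.379, median -0.08) or WT455 (0.412, median -0.22).

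Immediate early and handling stress genes were lower in 20 of 23 members, with a median of -0.64, and the list fell by camera (adjusted p = 9.35e-04, adjusted p = 0.747 with an estimated correlation), with 0 members passing either adjustment. Fos (-2.35 ± 0.94 SE), Hspa1a (-2.74 ± 1.46), Zfp36 (-1.42 ± 0.55) and Klf2 (-0.92 ± 0.27) are examples. WT453 lay 1.23 above the mean of the 6 libraries in this list, and without it the median was -0.41. Without WT453, Fos was -1.12, Hspa1a -0.86 and Zfp36 -0.78, whereas Fos was -2.98 without WT454 and -2.95 without WT455, and Hspa1a -4.06 without WT455.

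**Figure D3:**
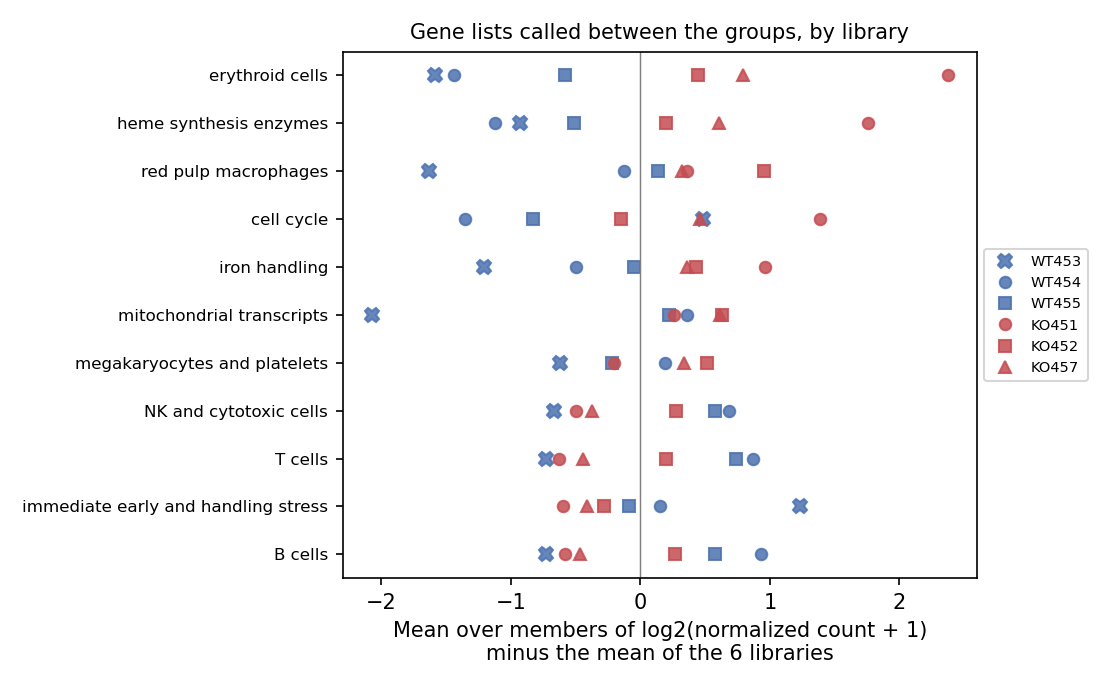
Mean over the members of each called gene list of log2(normalized count + 1), less the mean of the 6 libraries (x axis, log2 scale), for the 11 lists called by camera (y axis). Each point is 1 library, wild type in blue and WAS knockout in red, with WT453 as a cross. WT453 is at the low or the high end of most lists, and the erythroid list has all 3 knockout libraries above all 3 wild-type libraries.

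Immunoglobulin constant regions differed by isotype and in both directions. Of 12 measured genes 8 were higher and 4 lower, camera did not call the list (adjusted p = 0.122), and fry's mixed test for change in either direction did (adjusted p = 0.0269). Adjusted over the list alone 4 passed as higher and 1 as lower, and over all genes 0 passed. Igha, of IgA, was lower with a log2 fold change of -2.16 ± 0.41 (SE), from 9344 to 1936 CPM. Ighg3, of IgG3 (1.65 ± 0.34), the lambda chain gene Iglc1 (1.31 ± 0.25) and Ighm, of IgM (1.43 ± 0.44), were higher. Reads of Iglc1 can be shared with similar lambda genes. All immunoglobulin genes together took 3.91% ± 0.892 (SD, n = 3) of reads in knockout and 3.83% ± 1.26 (SD, n = 3) in wild-type libraries. In the type I interferon list, 17 of 27 members were higher and 10 lower (median 0.11, camera adjusted p = 0.611), and Rsad2 (2.44 ± 0.58) and Isg15 (1.68 ± 0.38), both induced by interferon, passed adjusted over the list alone. Without WT453 the median of that list was -0.33 and 0 members passed. The list of exocrine and endocrine pancreas, a neighbouring tissue, had 5 of 7 measured members higher and was called by fry's mixed test (adjusted p = 0.0317) but not by camera (adjusted p = 0.335). Its member Cela1 had a log2 fold change of 1.11 ± 0.26.

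The other lists were not called. Among myeloid cells the medians were -0.10 for mature neutrophils, 0.27 for neutrophil granules and precursors, 0.24 for monocytes, 1.05 for marginal zone macrophages, -0.04 for conventional dendritic cells, 0.07 for plasmacytoid dendritic cells, 0.02 for mast cells and basophils and 0.23 for eosinophils. Csf3r (-1.08 ± 0.31 SE) and Cxcr1 (-1.54 ± 0.42) were lower and Fpr1 (1.19 ± 0.40) was higher among neutrophil genes. Lymphoid lists had medians of -0.55 for marginal zone B cells, 0.50 for germinal centre B cells, 0.01 for plasma cells, -0.30 for regulatory T cells and 0.54 for follicular helper T cells and T cell activation. The remaining medians were -0.31 for MHC class II presentation, 0.15 for stem and progenitor cells, -0.39 for fibroblastic and reticular stroma, 0.46 for endothelium, -0.06 for fat tissue, -0.17 for the interferon gamma response, -0.26 for inflammatory cytokines and chemokines, 0.20 for complement and -0.36 for X inactivation and Y-linked transcripts. In the fat tissue list Fabp4 (1.54 ± 0.35) and Lpl (1.66 ± 0.51) passed adjusted over the list alone with all 6 libraries and 0 members without WT453. The median was 0.04 over 40 genes of the WASp complex and actin nucleation, of which Cttn, cortactin, had a log2 fold change of 1.35 ± 0.35. In the lists of plasma cells, conventional dendritic cells, mast cells and basophils, fat tissue and neighbours of Was, the median had the opposite sign to the mean. Neighbours of Was on the X chromosome had a median of -0.16, with Gata1 (1.79 ± 0.43), Slc38a5 (1.91 ± 0.49) and Ftsj1 (0.97 ± 0.31) higher. Without WT453 the median had the opposite sign for mature neutrophils (0.99), fibroblastic and reticular stroma (0.56), plasmacytoid dendritic cells (-0.51), plasma cells (-0.06) and neighbours of Was (0.04), and was 0.32 for marginal zone macrophages, with none of these called. Also without WT453 the lists of neutrophil granules and precursors (median 1.60, adjusted p = 2.02e-04) and stem and progenitor cells (0.28, adjusted p = 0.0139) were called higher, and MHC class II presentation (-0.86, adjusted p = 0.00326) and the interferon gamma response (-0.44, adjusted p = 0.0177) lower. With an estimated correlation and without WT453 none of these 4 was called (adjusted p = 0.738 for neutrophil granules and precursors, 0.735 for stem and progenitor cells, 0.750 for MHC class II presentation and 0.762 for the interferon gamma response).

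Of the 38 lists, 11 were called by camera, 7 higher and 4 lower, 0 with an estimated correlation and 0 by fry's directional test (smallest adjusted p = 0.344). The mean levels of 6 of the 38 lists did not overlap between the groups, where 10% of lists would be due to chance. Of single genes, 19.5% did not overlap. The 6 were the lists of erythroid cells, heme synthesis, iron handling, red pulp macrophages, complement and immediate early and handling stress genes. Some of them share members, such as Alas2 in the erythroid and heme synthesis lists. Exact permutation tests of these means gave p = 0.1 each and an adjusted p of 0.633. Each list's level depends on the mix of cells in the tissue, and no cell fractions were estimated.

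The libraries did not separate by group first. On principal components of the tested genes, PC1 held 39.2% of the variance and set WT453 (-184) apart from the other 5 libraries (21.6 to 55.1), and PC2 held 24.1%. Correlations across genes of WT453 with the other libraries were 0.906 to 0.921, and those among the other 5 were 0.944 to 0.971. WT453 had the highest share of reads from S100a8 and S100a9, which neutrophils make in large amounts, at 4.59%, against 0.277% in WT454 and 0.504% in WT455. KO457 had 3.21%. Mitochondrial transcripts took 1.48% of reads in WT453 and between 5.89% and 8.46% in the other 5 libraries. Among genes with a mean normalized count of at least 100, 240 were in WT453 over 4 times lower than in any other library and 64 were over 4 times higher, against at most 6 and 36 for any other library.

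**Figure D4:**
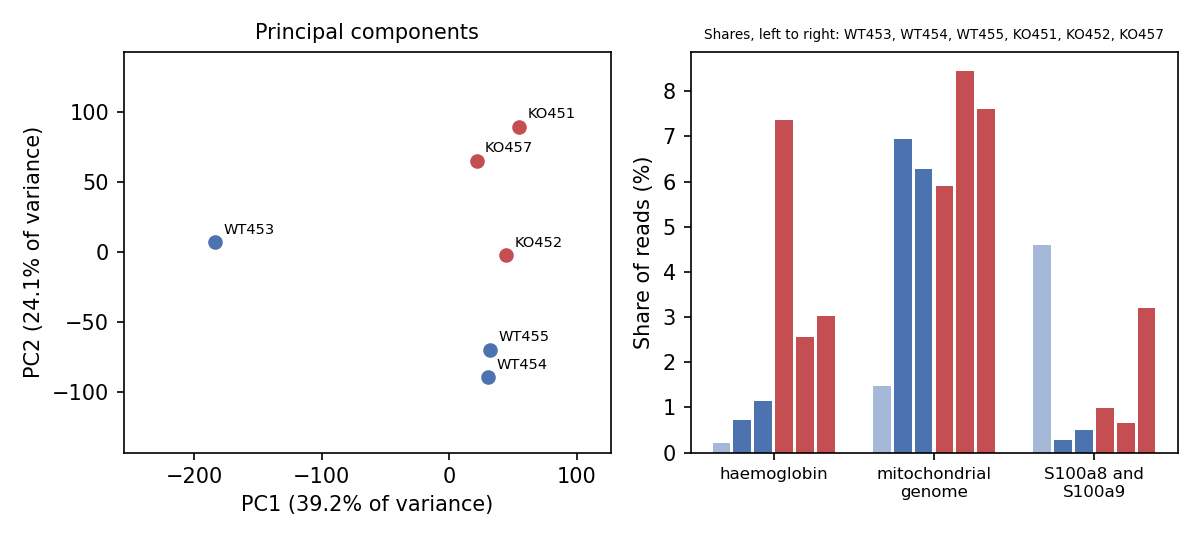
Left, the 6 libraries on the first 2 principal components of log2(normalized count + 1), wild type in blue and WAS knockout in red. Right, the percentage of reads from haemoglobin genes, the mitochondrial genome, and S100a8 with S100a9, 1 bar per library, with WT453 pale. WT453 lies alone at the left of PC1 (-184) and has 1.48% mitochondrial reads.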

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

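Genes changed, genes changed at least 2-fold and Was expression rested on few calls. Without 1 replicate each, genes changed ranged from 0 to 2, genes changed at least 2-fold from 0 to 2 and Was expression from a log2 fold change of -3.87 to -3.53 (adjusted p 0.0447 to 0.341). Without WT453 the 2 genes called were the same 2, and without any other library 0 were called. The other planned settings gave 2 or 3 genes changed, except 0 at a threshold of 0.01. Alternatives added after seeing the data moved the counts further. Library quality weights, which gave WT453 a weight of 0.160 and WT455 one of 4.70, gave 16 genes changed, 16 genes changed at least 2-fold and 17 gene lists. Voom on recovered reads gave 1 for genes changed and 1 for genes changed at least 2-fold. That gene was Was (voom, adjusted p = 0.0479), so Gm20716 lost its call. With a filter at 1 CPM, voom gave 0 and 0 with robust moderation, with Was expression at -3.66 (adjusted p = 0.0651), and 8 and 8 with quality weights. Rac1 was called in both settings with quality weights, in limma (adjusted p = 0.00888) and in voom (adjusted p = 0.0150). Ahdc1, mt-Rnr1, mt-Rnr2 and Gm4631 were called in both as well. Was kept its direction in every setting, with an adjusted p from 8.44e-05 to 0.341. The higher and lower calls were 0 and 2 in the main test, 7 and 9 with library quality weights and 4 and 4 in voom with quality weights. Scaling by library totals moved the median of all genes to -0.17, where it was -0.03 in the main test, and gave 3 genes changed, all lower. The cause of these differences was not tested.

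Gene lists numbered 11, and 9 to 13 without 1 replicate each. The number was 0 with camera at an estimated correlation, 0 with the same test without WT453, which was added after seeing the data, and 0 with fry. For the erythroid cells list the adjusted p was 0.747 with an estimated correlation and 0.344 with fry, with the median at 2.58 in both because only the test changed. Without WT453 and with an estimated correlation it was 0.735, with a median of 2.29. Its median ranged from 1.94 with library quality weights to 2.98 without KO452. The list was past the threshold in the other 24 alternatives, all of which used camera at the preset correlation between genes. The estimated correlation of its members was 0.76, so these 24 cannot show whether the call holds without the preset. Among the other called lists 220 values under alternatives kept their direction and call, all at the preset correlation. Another 50 kept their direction and lost the call. Among named genes 0 calls turned in direction, while 15 values under alternatives gained a call and 14 lost one. Adnp, not called, was 2.55 in the main test and turned lower without WT453 (-0.86, the range without 1 replicate each being -0.86 to 4.30), also with the filter at 1 CPM (-0.86), with library quality weights (-0.92) and in voom with quality weights (-1.06). Each of these settings takes out or down-weights WT453, in which Adnp was near 0.

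No paired analysis was possible because the groups share no animal numbers. Count tests, TMM scaling and tests built on them were planned for deposited counts and were not run, since the deposited values are log2 values. The recovered reads would have allowed them, and of tests for counts only limma voom was run on those reads. Depth limited genes of a few reads, for which 3 reads stand for up to 0.0978 CPM.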

Other observations

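Early B cell genes were not among the lists fixed before the data were examined. Rag2, part of the recombinase, had a log2 fold change of 3.72 ± 1.03 (SE), Igll1, of the surrogate light chain, 4.19 ± 1.52, Vpreb1, of the same complex, 1.78 ± 1.01, and Dntt 1.03 ± 0.46. All 4 were higher in knockout spleens, with mean levels of at most 7.10 CPM, and 0 passed limma's adjusted threshold. They were chosen after their values were seen. KO457 carries much of this, with Igll1 at 12.9 CPM against 1.59 in KO451 and 0.899 in KO452. Without KO457 the log2 fold changes were 3.05 for Igll1, 2.99 for Rag2 and 0.56 for Vpreb1. Rag2 was 2.78 without WT453, and Igll1, with 0 reads in WT455, was also over 1.5 times lower in fold change without WT455. In the other direction, Igll1 was 5.01 without KO452 and 5.68 without WT453, and Vpreb1 2.47 without KO451. The proliferation genes Mki67 (1.16 ± 0.73, 1.87 without WT453) and Top2a (1.03 ± 0.55) did not pass either.

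Of the tests below, the one on short RNA genes was written down before its result was seen, and all others were chosen after the values they concern had been seen. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 2 genes and the highest other split 1, both for genes changed and for genes changed at least 2-fold, and 1 split, the real one, gave as many. For gene lists, the real split called 11 and the highest other 23, and 9 of the 10 splits gave at least 11. Lists were called in every split of these libraries at the preset correlation, so their number does not set the real split apart. The cause was not tested, and the other splits were not run with an estimated correlation. The median of the erythroid list was 2.58 in the real split and at most 1.87 in size in another. At an unadjusted p under 0.05 the split of KO451, KO457 and WT453 against the rest gave 3077 genes, above the 2420 of the real split.

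WT453 stood apart from the other 5 libraries. Overlapping gene models do not account for that as a whole: in the 9775 genes that overlap no other gene, its highest correlation with another library was 0.923, below the lowest among the other 5, 0.944. Nor do trends on GC content and transcript length, since after their removal the same values were 0.922 and 0.944. A larger share of connective tissue stays open, since WT453 was the highest library in 17 of 24 stroma genes, where at least 20 would have spoken for it and fewer than 12 against it. The mean of the stroma list leaned towards it. WT453 lay 1.83 above the mean of the 6 libraries on the log2 scale, and the next highest, KO457, 0.19 above. In WT453 alone, 8 genes were near 0 and 10 were present where the other 5 libraries were the reverse, and 12 of these 18 overlap another gene, against 53.8% of genes with a mean normalized count of at least 100. No other biological explanation within the wild-type group was tested.

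The higher level of red cell genes in knockout spleens does not rest on WT453 alone, as the median log2 fold change without it was 2.29. A lower share of other cells would raise all remaining cell types alike, but the lower quartile of the erythroid genes, 2.06, lay above the highest median of 11 lists of other non-lymphoid cells, 1.16. Blood left in the tissue, with no nucleated precursors, stays open: 10 regulators of those precursors had a median of 1.69 (0.97 less 2 standard errors over genes), but the 5 outside the erythroid list had one of 0.63 (-0.10 less 2 standard errors). Of the 10 regulators 9 were higher, among them Klf1 (2.78), Tal1 (2.52), Gata1 (1.79) and Epor (1.74) of the erythroid list. Outside that list Gfi1b was at 1.97, Zfpm1 at 1.63, Lmo2 at 0.63, Myb at 0.42 and Kit at 0.08. Nfe2, of the list, was at -0.75, and at -0.01 without WT453. Standard errors over genes leave out the spread between animals. A candidate explanation, as a hypothesis only, is more nucleated red cell precursors in the knockout spleens, which a count of nucleated erythroid cells in further spleens would test, but the blood left in the tissue and differences between animals unrelated to genotype stay open with 3 mice per group.

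The mitochondrial ribosomal RNAs took 0.548% ± 0.0755 (SD, n = 3) of reads in knockout and 0.175% ± 0.0405 (SD, n = 3) in wild-type libraries, and an exact permutation test gave p = 0.1, and 0.3 after adjustment over 6 shares. More mitochondrial transcripts altogether stay open. The ratio of ribosomal to messenger RNA of mitochondria was 2.63 times as high in knockout libraries without WT453, but 1.56 times with it, and the ratio of WT453, 9.59 per 100 messenger reads, lay above all knockout libraries. Less complete selection of polyadenylated RNA would raise other RNAs without a poly(A) tail, but 257 short RNA genes had a median of -0.39 (-0.50 to -0.27 at 2 standard errors over genes), and -0.12 without WT453. Reads on such genes can come from the introns that hold them, which limits that test. Its standard errors over genes also leave out the spread between animals. A difference in how the groups were prepared or processed was not tested, since it cannot be separated from genotype.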
